A study of Mus musculus with 44 samples.

How the data were processed

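The series held 44 samples from cultured mouse cortical neurons: 12 RNA-seq libraries (3 each of bicuculline, tetrodotoxin and untreated cells at 16 days in vitro, and 3 at 5 days), 9 RNA-seq libraries of a time course, 12 5C libraries of the 24 h states (4 per state), 5 5C libraries of the time course, and 6 ChIP-seq libraries (1 H3K27ac immunoprecipitation and 1 input per state). Bicuculline is written Bic and tetrodotoxin TTX throughout. Libraries of a group are numbered in the order of the deposited columns or samples. In the RNA-seq of the 24 h states and of day 5, libraries 1 and 2 of each state carried the earlier culture date and library 3 the later one, and the labels state that the replicates span 2 culture batches. In the 5C of the 24 h states, libraries 1 and 2 carried the earlier date and 3 and 4 the later one.

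The deposited RNA tables give TPM (transcript abundances scaled to a fixed total per library) per RefSeq transcript, made by the authors with Salmon, per the file names and the submitters' processing notes. Every column summed to the same fixed total, so no read counts were available although the name of the 24 h table mentions counts, and the sequencing depth of the RNA libraries is unknown. Libraries came from ribosome-depleted, stranded total RNA, per the labels' protocols. The deposited 5C files give a raw count of ligation products per pair of 5C primers, and the reads were aligned with Bowtie, per the submitters' processing notes. The deposited H3K27ac lists are broad peaks in mm9, called by the authors with MACS2 per the header names and peak names, and each peak carries a score, a fold enrichment over background, and −log10 p and q values. The peak names, per the deposited files, also hold a word for downsampled reads, and no other step before the peak calls is recorded. No alignment or peak calling was repeated.

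Transcript values were summed per gene symbol through the RefSeq accessions: 35499 of the 35786 transcripts matched a symbol in the RefSeq gene table supplied with the data, giving 24328 genes. That table describes the assembly GRCm38.p6 while the deposited peaks and primers are in mm9, so it was used for names and neighbours only. Genes were therefore not placed in 5C windows or assigned to peaks.

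The tests planned for RNA were count models. Because the table holds TPM, limma 3.58.1 was used instead (lmFit and eBayes with trend) on log2 of the trimmed-mean-scaled TPM plus a pseudocount of 1, with scaling factors from edgeR 4.0.16, for genes with a TPM of 1 or more in at least 3 libraries. Bic, TTX and untreated libraries formed 1 fit with 3 pairwise contrasts and another contrast of untreated cells against the midpoint of Bic and TTX. Untreated cells at day 16 and cells at day 5 formed a separate fit. The time course was fitted with limma on unscaled log2(TPM + 1) for genes with a TPM of 1 or more in at least 2 libraries, each time against 0 min, and the single 5 min library was assumed to vary like the others. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. TPM means and SD for the 24 h states and for the ages are of the scaled values, and SE is that of the fitted log2 change. All tests were 2-sided.

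A set of 20 gene lists (activity, loci, synapse, excitability, metabolism, development, cell types and stress) was fixed before the data were examined. So were the alternatives not described as added. The tests were fixed then too, except the limma fits that replaced the count models and those described as chosen later. Each list with 3 or more tested members was tested with camera (limma) at a preset correlation between genes of 0.01 and again with the estimated correlation, adjusted over the lists of a contrast. Member counts are given over all genes tested and adjusted over the list alone. Named genes followed a fixed rule: the 10 higher and 10 lower called genes with the largest change (5 and 5 in the contrasts with untreated cells) that had a mean TPM of 5 or more in a group and no overlap between the groups, the up to 4 members of each list with the smallest p, and the 6 genes of the 5C loci. Chance gives no overlap between 3 and 3 libraries for 10% of genes. Symbols of predicted genes and of micro and small nucleolar RNAs were counted but passed over for naming.

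To check whether the culture batch stated in the labels moved libraries together, deviations from the state means were correlated across genes. Libraries of different states from the same culture correlated at 0.216 to 0.693 (15 pairs, median 0.382), and libraries from different cultures at −0.549 to −0.339 (12 pairs). A fit with culture as a block was therefore added after the data were seen, and its values stand beside many, but not all, of the results that it moved.

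The 5C counts were summed over pairs of 20 kb windows within each of 6 regions, with a mean count of 10 or more per library. An edgeR quasi-likelihood F-test used as offset the library's total in the region and window distance (distances with under 3 pairs or a total under 200 were merged with the next longer). Observed over expected values divide a count by the mean expected from region and distance. Outlier primer pairs were defined as primer pairs with more than 50 times the library's mean of their region and distance class and more than 1000 counts in at least 6 of the 12 libraries. Window pairs were classed by whether their ends held Bic peaks absent from the TTX list (Bic-only), TTX peaks absent from the Bic list (TTX-only) or peaks shared by Bic and TTX. The untreated list played no part in these classes. Class means were compared by exact permutation of 4 against 4 libraries, whose smallest p is 2 in 70. Peaks at the ends of called pairs were compared with 2000 sets, and time course changes with 10000 sets, of window pairs matched on region and distance. Peaks were shared when they overlapped by 1 bp or more.

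The tests were tested on simulated data with 200 changed genes or window pairs. At a 2-fold change the limma fit recovered 63.8% of changed genes for Bic against TTX and 59.7% for the 2 ages, the 5C test recovered 58.3% of changed window pairs, and the time course fit recovered 0% at 5 min and 5.88% at 360 min (76.1% at a 4-fold change). Alternatives covered scaling, pseudocount, low-value filters, window size, batch and replicate terms, DESeq2 1.42.0 for the 5C counts, peak thresholds, and leaving out each library in turn. Total 5C counts ran from 18796626 to 36045855 in the 24 h states and from 41287514 to 49092684 in the time course. Scripts ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. ChIP-seq input libraries had no deposited values and were not used.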

Results

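Cortical neurons from embryonic mice were grown in culture. At 16 days in vitro they were compared after 24 h with bicuculline (Bic, 10 µM, a blocker of GABA-A receptors that raises network firing), with tetrodotoxin (TTX, 1 µM, a blocker of voltage-gated sodium channels that silences firing) or without either. RNA-seq covered these 3 states (3 libraries each) and cells at 5 days in vitro (3 libraries). A separate set of cultures was silenced with TTX for 24 h and then given Bic for 0, 5, 20, 60 or 360 min, with 2 RNA-seq libraries per time and 1 at 5 min. H3K27ac ChIP-seq, which marks active promoters and enhancers, had 1 peak list per state. 5C counts ligation products between primer-tagged restriction fragments as a measure of their contact, and it covered 6 regions with 4 libraries per state and 1 per time of the time course. Total 5C counts ran from 18796626 to 36045855 in the 24 h states. The depth of the RNA libraries is unknown because the tables give TPM.

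Neurons with raised activity differed from silenced neurons in activity-regulated genes. The immediate early transcription factor Fos had a TPM of 236 ± 73.3 (SD, n = 3) in Bic and 8.00 ± 1.16 in TTX, with 69.3 ± 33.0 in untreated cells. Bdnf, which encodes a secreted neurotrophin, stood at 37.0 ± 5.80 in Bic and 1.44 ± 0.315 in TTX, a log2 change of 3.96 (SE 0.47). Nptx2, a secreted protein that gathers AMPA receptors at synapses, rose from 11.0 ± 3.97 to 411 ± 147. Txnip, an inhibitor of thioredoxin, ran the other way and stood at 45.6 ± 15.7 in TTX and 4.33 ± 1.48 in Bic. Of 13623 genes tested in limma, 2057 were higher and 1497 lower in Bic than in TTX, and 10069 were not called. Of these, 731 higher and 320 lower genes passed a 2-fold change.

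Among 26 tested immediate early genes 21 were higher in Bic than in TTX and 0 were lower (23 and 1 adjusted over the list alone). For this list camera gave an adjusted p = 3.27e-12, and an adjusted p = 0.277 with an estimated correlation. Fosl2 rose by 3.28, Gadd45g by 3.76 and Arc, a regulator of AMPA receptor uptake, by 3.53 on the log2 scale. Of 30 late activity genes 28 were higher and 0 lower (28 and 0 adjusted over the list alone), with camera at an adjusted p = 1.13e-19, and an adjusted p = 0.0995 with an estimated correlation. Examples were Crh, the corticotropin-releasing hormone, at a log2 change of 2.84, the phosphatase Dusp4 at 4.01 and Stac at 2.64.

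The largest increases between TTX and Bic were those of Alkal2, Lce1g, Krt6a, Cartpt, Crct1, Lce1i, Atf3, Nptx2, Lce3c and Fos. Alkal2, a ligand of the ALK receptor, stood at 0.421 ± 0.145 TPM in TTX, 25.1 ± 9.83 in untreated cells and 178 ± 69.9 in Bic (log2 change 6.89, SE 0.35, limma adjusted p = 1.55e-05). The neuropeptide precursor Cartpt rose from 2.76 ± 0.436 to 161 ± 12.9. Lce1g, Lce1i, Lce3c, Crct1 and Krt6a are genes of the epidermis. Lce1g stood at 106 ± 40.2 TPM in Bic, and Lce3c was listed at 0 in all TTX libraries. The Lce genes are near-identical copies, so the split of reads between them is uncertain. The largest decrease was that of Rasl10a, a small GTPase of the Ras family, from 48.5 ± 5.47 to 2.44 ± 0.665 TPM (log2 change −3.86, SE 0.17, limma adjusted p = 8.05e-06). Hrk, a cell death activator (−3.19), Txnip (−3.11), Matn2, Trp53i11, Slc44a5, Pik3ip1, Syt17, Tef and Elk1 followed.

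**Figure D1:**
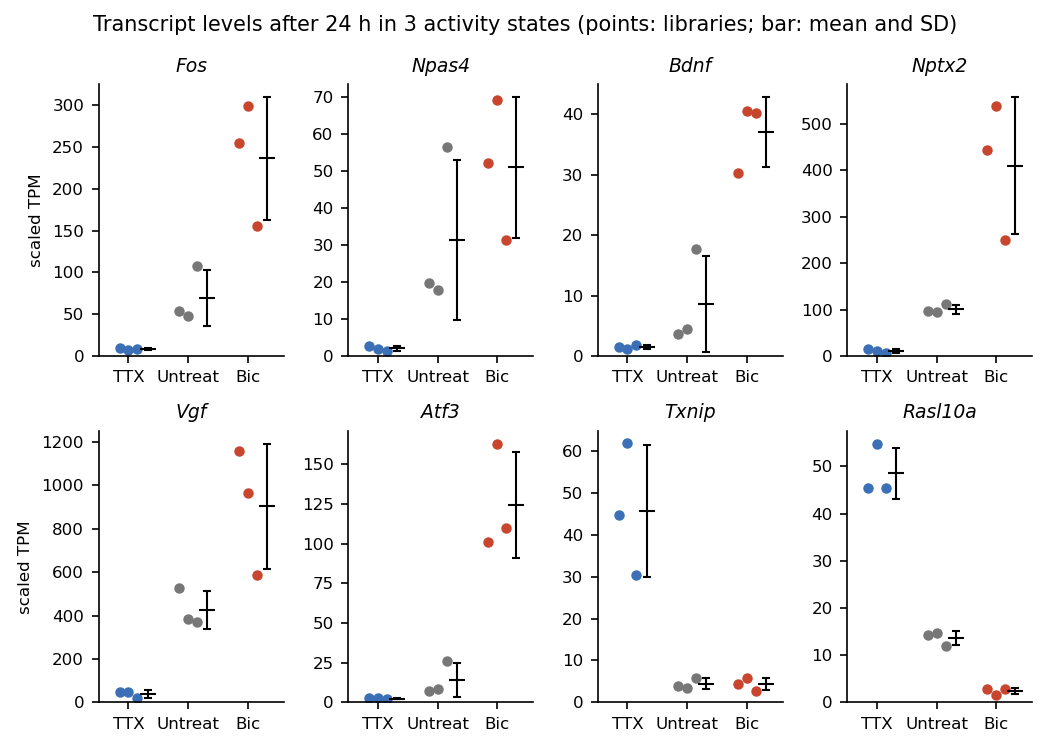
Scaled TPM of 8 activity-linked genes in each library of the TTX, untreated and Bic states, with points for libraries and the mean and SD for each state. Fos stood at 8.00 in TTX, 69.3 in untreated and 236 in Bic cells, while Txnip and Rasl10a were highest in TTX.

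Stress response genes were also higher in Bic than in TTX. The integrated stress response had 8 genes higher and 0 lower of 13 (9 and 0 adjusted over the list alone), with camera at an adjusted p = 1.2e-05, and an adjusted p = 0.195 with an estimated correlation. The asparagine synthetase Asns rose from 124 ± 1.38 to 342 ± 8.60 TPM, and Psat1, an enzyme of serine synthesis (1.65), Chac1 (3.04) and Ddit3 (1.92) rose as well. Heat shock genes had 6 higher and 0 lower of 11 (6 and 0 adjusted over the list alone), with camera at an adjusted p = 0.0145, and an adjusted p = 0.195 with an estimated correlation. Hspa1b stood at 41.7 ± 11.1 TPM in Bic and 6.88 ± 1.43 in TTX. Hspa1a (1.58) is a near-identical copy of Hspa1b, so the values of this pair are uncertain. The heat shock count was 3 without TTX library 1, 2 without TTX library 2, 3 without Bic library 1, 2 without Bic library 2 and 3 without Bic library 3.

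Immature neuron genes had 7 lower and 1 higher of 18 (8 and 1 adjusted over the list alone), with camera at an adjusted p = 0.00543, and an adjusted p = 0.195 with an estimated correlation. Neurod2, a transcription factor of cortical excitatory neurons, fell from 60.2 ± 5.18 in TTX to 12.8 ± 0.450 TPM in Bic. Nnat fell from a mean of 2245 to 764 TPM, and Neurod1 (−1.13) and Stmn1 (−0.62) were also lower. Cholesterol synthesis genes had 6 higher and 1 lower of 19 (6 and 1 adjusted over the list alone), with camera at an adjusted p = 0.0289, and an adjusted p = 0.457 with an estimated correlation. They were led by Cyp51 (1.74) and Msmo1 (1.40), and 10 were higher with culture as a block.

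Synapse genes were called in both directions. Ionotropic glutamate receptors had 1 higher and 2 lower of 14 (1 and 4 adjusted over the list alone), and Gria1 fell from 80.8 ± 1.71 in TTX to 44.7 ± 0.539 TPM in Bic. GABA signalling had 3 higher and 2 lower of 17, with Gad1, an enzyme that makes GABA, at 146 ± 10.4 in TTX and 288 ± 54.4 in Bic. Synaptic adhesion had 2 higher, Slitrk2 (1.27) and Slitrk5 (1.02), and 2 lower of 21. Presynaptic vesicle genes had 3 and 3 of 23, such as Slc17a6 (1.97) and Syn2 (−0.95). Postsynaptic scaffolds had 2 higher and 0 lower of 20 (0 and 0 adjusted over the list alone), among them Homer1 (1.04). Sodium and potassium channels had 5 and 4 of 24, with Kcna4 at 1.27. For GABA signalling, adhesion, presynaptic genes and channels the counts were the same adjusted over the list alone, and camera gave adjusted p values from 0.69 to 0.94 over these 6 lists. With culture as a block the counts, higher and lower, were 3 and 6 for glutamate receptors, 9 and 4 for GABA signalling, 4 and 6 for adhesion, 5 and 9 for presynaptic genes, 4 and 8 for scaffolds, and 7 and 10 for channels.

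At the 5C loci Fos, Bdnf and Arc rose, and Nlgn3, a postsynaptic adhesion protein, fell from a mean of 43.6 to 22.6 TPM (limma adjusted p = 0.0311). Syt1 (−0.35) was not called. These 3 higher and 1 lower of 6 were the same adjusted over the list alone (camera adjusted p = 0.18). Cell type markers had 4 higher and 3 lower of 12 for excitatory neurons, 2 and 1 of 14 for inhibitory neurons, 0 and 1 of 13 for astrocytes, 0 of 4 for the oligodendrocyte lineage and 0 of 4 for vascular cells. Of 5 microglial genes 1 was higher, Csf1r from a mean of 0.670 to 2.40 TPM. Camera gave these marker lists adjusted p values from 0.468 to 0.974. Adjusted over the list alone the astrocyte counts were 0 and 0, and the others did not move. With culture as a block astrocyte markers had 3 higher and 7 lower, excitatory markers 4 and 7, and inhibitory markers 5 and 2. Fewer than 3 genes of proliferating cells passed the expression filter in these states, so that list was not tested here.

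Libraries of the same culture deviated together, and with culture as a block limma called 3838 genes higher and 3523 lower in Bic than in TTX. Without Bic library 1 the higher count was 1275 and without Bic library 2 it was 1231, while without TTX library 2 the lower count was 896. TTX library 3 carried 9.28% of its TPM on the 45S ribosomal RNA precursor, against 1.41% to 2.57% in the other libraries of these states. The small RNA Rpph1 took 12.8% to 21.8% of the TPM of all 12 libraries.

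Silenced neurons had lower values than untreated ones for activity genes and sterol synthesis genes. Vgf, a secreted neuropeptide precursor, fell from 427 ± 86.7 TPM (SD, n = 3) in untreated cells to 38.8 ± 16.8 in TTX. The activity-induced transcription factors Nr4a1 (42.5 ± 9.88 to 2.35 ± 1.35) and Npas4 (31.3 ± 21.7 to 2.01 ± 0.646) fell as well. Mvd, an enzyme of the mevalonate pathway, stood at 124 ± 11.9 untreated and 24.2 ± 1.71 in TTX (log2 change −2.31, SE 0.10, limma adjusted p = 5.72e-05). Txnip rose from 4.45 ± 1.32 to 45.6 ± 15.7 (log2 change 3.07, SE 0.31, limma adjusted p = 0.00126), and Slc44a5 (2.62), Cdkl4 (2.07), Hrk (2.01) and Matn2 (1.95) were next. In limma 501 genes were higher and 980 lower in TTX than in untreated cells, and 12142 were not called.

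Immediate early genes had 0 higher and 15 lower of 26 in TTX (0 and 18 adjusted over the list alone). Camera gave an adjusted p = 2.63e-10, and an adjusted p = 0.367 with an estimated correlation. Fos was at −2.88 and Arc at −2.55 on the log2 scale. Late activity genes had 0 higher and 17 lower of 30 (0 and 24 adjusted over the list alone), with camera at an adjusted p = 6.5e-15, and an adjusted p = 0.099 with an estimated correlation. Dusp4 was at −2.72 and Nrn1 at −1.31, while Bdnf at −1.68 was not called (limma adjusted p = 0.0567). Cholesterol synthesis genes had 0 higher and 14 lower of 19 (0 and 16 adjusted over the list alone), under every scaling tried. Camera gave this list an adjusted p = 4.99e-16, and 0.03 with an estimated correlation, or 0.402 with culture as a block as well.

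The integrated stress response had 0 higher and 7 lower of 13 in TTX (0 and 8 adjusted over the list alone), and 4 lower on unscaled TPM. Camera gave it an adjusted p = 0.000203, and an adjusted p = 0.295 with an estimated correlation. Its transcription factor Atf4 fell from 299 ± 15.3 in untreated cells to 108 ± 26.2 TPM. Glutamate receptors had 2 higher, Gria1 (0.52) and Grin2b (0.55), and 0 lower of 14, the same adjusted over the list alone (camera adjusted p = 0.105). GABA signalling had 0 higher and 2 lower of 17, Gabrd (−1.33) and Gad1 (−0.80), and 2 and 2 adjusted over the list alone. Its median log2 change was 0.3, and camera gave an adjusted p = 0.746. With culture as a block the counts, higher and lower, were 7 and 1 for glutamate receptors and 8 and 4 for GABA signalling.

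The immediate early count in TTX was 9 without untreated library 1, 8 without untreated library 2, 8, 7 and 8 without TTX library 1, 2 or 3, and 9 without Bic library 1. Genes higher and lower in TTX numbered 146 and 327 without untreated library 1, 140 and 381 without untreated library 2, 165 and 456 without TTX library 1, 174 and 467 without TTX library 2, and 307 and 631 without TTX library 3. Bic libraries enter this contrast through the spread, the scaling and the filter, and the counts were 311 and 738 without Bic library 1 and 327 and 781 without Bic library 2. With culture as a block they were 3490 and 3119. On unscaled TPM the median of all genes moved by 0.151 on the log2 scale and 702 genes were higher and 372 lower. Upper-quartile scaling gave 728 and 703, so the balance of directions depends on the scaling.

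Active neurons had higher values than untreated ones for activity genes and lower values for sterol synthesis genes. Cartpt (log2 change 4.24), Atf3 (3.27), Inhba, a subunit of activin (2.65), Gadd45g (2.53) and Jun (a mean of 31.3 to 174 TPM) were higher in Bic. The activity-regulated transcription factor Egr3 was lower (a mean of 16.7 to 3.75 TPM; limma adjusted p = 0.00364). Fdps, an enzyme of isoprenoid synthesis, fell from 340 ± 37.3 (SD, n = 3) to 85.3 ± 3.19 TPM (log2 change −1.98, SE 0.11, limma adjusted p = 5.66e-05). The largest increases were those of the epidermal genes Lce1g (6.21), Lce1i (5.26), Crct1 (5.24), Krt6a (4.97) and Lce3c (4.82). The largest decreases were those of Syt17 (40.9 ± 7.38 to 8.62 ± 1.11), Rasl10a (−2.10), the adenosine receptor Adora2a (−2.08), Sema4a (−1.99) and Fdps. In limma 1596 genes were higher and 1405 lower in Bic than in untreated cells, and 10622 were not called.

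Immediate early genes had 12 higher and 2 lower of 26 in Bic (15 and 2 adjusted over the list alone), with Fos at 1.80 and Arc at 0.99. Late activity genes had 21 higher and 1 lower of 30 (24 and 1 adjusted over the list alone), with Bdnf at 2.28 and Crh at 1.71. Camera gave these lists adjusted p = 0.000357 and 1.53e-10, and adjusted p = 0.647 and 0.132 with an estimated correlation. Cholesterol synthesis had 0 higher and 12 lower of 19 (0 and 13 adjusted over the list alone), with camera at an adjusted p = 3.09e-08, and an adjusted p = 0.114 with an estimated correlation. Immature neuron genes had 2 higher and 10 lower of 18 (2 and 11 adjusted over the list alone), with camera at an adjusted p = 0.000357, and an adjusted p = 0.114 with an estimated correlation. The neuronal tubulin Tubb3 fell from a mean of 2035 to 1058 TPM. On unscaled TPM 5 immature neuron genes were lower, and without Bic library 2 6 were.

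The integrated stress response had 8 higher and 0 lower of 13 in Bic (8 and 0 adjusted over the list alone), with camera at an adjusted p = 0.00116, and an adjusted p = 0.332 with an estimated correlation. The count was 5 without untreated library 2, Bic library 1 or Bic library 2. Nlgn3 was lower (−0.90, limma adjusted p = 0.04), and Syt1 (−0.07) was not called. Genes higher in Bic than in untreated cells numbered 841 without Bic library 1, 780 without Bic library 2, 915 without untreated library 1 and 891 without untreated library 2. Genes lower numbered 642 without untreated library 1, 687 without untreated library 2 and 922 without Bic library 2. With culture as a block 4188 were higher and 3415 lower. On unscaled TPM the median of all genes moved by 0.219 on the log2 scale, and 2497 genes were higher and 458 lower.

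Many genes of cholesterol synthesis were higher in untreated cells than in the silenced or the active state, with 14 of 19 called lower in TTX and 12 of 19 in Bic. Cyp51 was an exception, with a mean of 34.7 TPM in untreated cells, 13.6 in TTX and 46.5 in Bic. Acat2, the first enzyme of the mevalonate pathway, stood at 120 ± 10.0 TPM (SD, n = 3) in untreated cells, 49.2 ± 0.807 in TTX and 43.8 ± 0.379 in Bic. Mvd stood at 124 ± 11.9, 24.2 ± 1.71 and 35.8 ± 1.64, and Fdft1, the squalene synthase, at 134 ± 13.3, 39.0 ± 3.82 and 41.5 ± 2.75. Of 19 cholesterol genes 14 lay above the midpoint of Bic and TTX and 0 below (17 and 0 adjusted over the list alone), by 2.04 for Mvd, 2.01 for Fdps, 1.71 for Fdft1 and 1.35 for Acat2 on the log2 scale. Camera gave an adjusted p = 3.13e-15, and 0.0343 with an estimated correlation. The count was 12 on unscaled TPM, 13 with upper-quartile scaling and 18 with culture as a block, where the estimated correlation gave an adjusted p = 0.35. Immature neuron genes lay above the midpoint for 6 and below for 2 of 18 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0983), and above for 3 on unscaled TPM or without untreated library 1.

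In limma 874 genes lay above the midpoint and 817 below it. The counts were 133 and 149 without untreated library 1, 174 and 167 without untreated library 2, 570 and 315 without Bic library 1, 560 and 323 without Bic library 2, 607 and 422 without TTX library 1, and 591 and 523 without TTX library 2. They were 3245 and 3766 with culture as a block. On unscaled TPM the median moved by −0.176 and 233 genes lay above and 1562 below, and with upper-quartile scaling 632 lay above and 928 below.

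**Figure D2:**
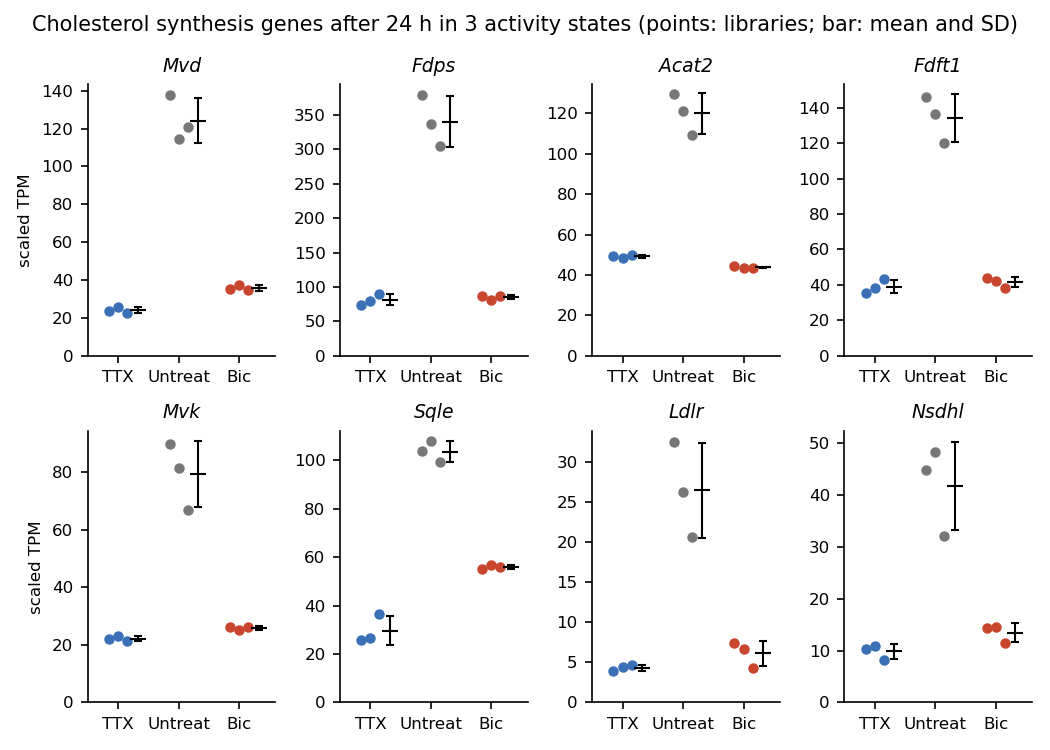
Scaled TPM of the 8 cholesterol genes with the smallest p for untreated cells against the midpoint of Bic and TTX, a choice that favours genes high in untreated cells. Values are shown for each library of the TTX, untreated and Bic states, with points for libraries and the mean and SD for each state. Untreated libraries were the highest for each gene, with Acat2 at a mean of 120 against 49.2 in TTX and 43.8 in Bic.

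Between 5 and 16 days in vitro, untreated neurons gained transcripts of mature synapses and lost those of dividing cells. Pvalb, a calcium buffer of fast-spiking interneurons, rose from 0.893 ± 0.489 TPM (SD, n = 3) at day 5 to 72.9 ± 31.4 at day 16 (log2 change 5.22, SE 0.38, limma adjusted p = 0.000158). Cckbr, a receptor for cholecystokinin, rose from a mean of 0.690 to 40.5, and the neuronal surface protein Thy1 from a mean of 40.3 to 660. The smooth muscle actin Acta2 fell from 345 ± 31.5 to 2.76 ± 1.00, and Cdk1, a kinase of cell division, from 45.2 ± 3.36 to a mean of 0.260. In limma 3071 genes were higher and 2880 lower at day 16 of 13408 tested, and 7457 were not called. Of these, 1386 higher and 1366 lower genes passed a 2-fold change.

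Most genes of the presynaptic vesicle machinery (21 higher and 0 lower of 23), postsynaptic scaffolds (16 and 1 of 20), GABA signalling (14 and 0 of 16) and sodium and potassium channels (17 and 0 of 24) rose. Camera gave these lists adjusted p = 8.21e-08, 7.23e-05, 7.39e-06 and 1.48e-06, and adjusted p = 0.188, 0.237, 0.188 and 0.138 with an estimated correlation. Adjusted over the list alone the counts were 22 and 0, 18 and 1, 15 and 0, and 17 and 0, and GABA signalling had 9 higher without day 5 library 1. Syn2 rose from a mean of 64.7 to 422 TPM and Slc17a7, the vesicular glutamate transporter of the cortex, from 37.2 to 538. Gad1 rose from 42.8 ± 1.65 to 259 ± 9.19 and Scn2b by 3.87 on the log2 scale, while the scaffold Homer3 fell from a mean of 27.2 to 4.53. Glutamate receptors (6 and 1 of 15), adhesion genes (9 and 0 of 21) and inhibitory neuron markers (8 and 0 of 14) had the same counts adjusted over the list alone. Camera gave them adjusted p = 0.00557, 0.00074 and 0.00174, and adjusted p = 0.188 each with an estimated correlation. With culture as a block the counts were 12 and 1 for glutamate receptors and 15 and 0 for adhesion genes. Grin1 was at 2.00, Grin2c at −1.12 and the interneuron peptide Vip at 3.02 on the log2 scale. Excitatory markers had 2 higher and 4 lower of 12, the same adjusted over the list alone (camera adjusted p = 0.788), and the lower ones numbered 2 without untreated library 1 or day 5 library 1 or 2, and 1 without untreated library 2.

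Activity genes were also higher at day 16, with 13 immediate early genes higher and 4 lower of 26 and 20 late activity genes higher and 0 lower of 29. Camera gave adjusted p = 0.0164 and 1.36e-08, and adjusted p = 0.459 and 0.188 with an estimated correlation. Adjusted over the list alone the counts were 13 and 5, and 24 and 0. Arc rose by 3.66, Egr4 by 4.00 and Nptx2 by 3.51 on the log2 scale. The 4 lower immediate early genes numbered 2 without untreated library 1 or 2 or day 5 library 1, and 1 without day 5 library 2. At the 5C loci Arc, Fos (1.53), Bdnf (2.17) and Syt1, the calcium sensor of vesicle release (a mean of 26.4 to 130), were higher, and Nlgn3 (0.52) was not called. These 4 of 6 were the same adjusted over the list alone, with camera at an adjusted p = 0.00768, and an adjusted p = 0.245 with an estimated correlation. Immature neuron genes had 1 higher and 14 lower of 18 (2 and 14 adjusted over the list alone), with camera at an adjusted p = 5.18e-05, and an adjusted p = 0.188 with an estimated correlation. Igfbpl1 was at −3.81, Dpysl3 at −2.20 and Tubb2b at −2.04.

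Genes of dividing, microglial and vascular cells fell between day 5 and day 16. Proliferation genes had 11 of 11 tested lower, microglial genes 7 of 7 and vascular genes 5 of 5, from lists of 12, 12 and 13. All were the same adjusted over the list alone. Genes near 0 at day 16 passed the filter only through the day 5 libraries, so they could be called lower only. Camera gave adjusted p = 8.21e-08, 7.04e-05 and 3e-04, and adjusted p = 0.188, 0.216 and 0.188 with an estimated correlation. Examples were Cdk1 (−5.19) and Aurkb (−5.02), the complement gene C1qa from a mean of 18.9 to 1.60 TPM, and Tagln (−4.92). Leaving out any day 5 library gave 4 microglial calls, and leaving out day 5 library 1, 2 or 3 gave 2, 2 and 3 vascular calls. The filter kept its minimum of 3 libraries in these fits, so genes found at day 5 alone left the test. The labels state that the mitotic blocker cytosine arabinoside was added at day 4. Histone genes were among the largest decreases, such as H3c3 (937 ± 151 to 3.36 ± 0.634 TPM), H3c2 and H2ac12, and these are near-identical copies whose single values are uncertain.

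Oligodendrocyte lineage genes had 1 higher, Mbp at 0.99, and 4 lower of 7, among them Cspg4 at −2.75, the same adjusted over the list alone. Camera gave an adjusted p = 0.0244, and an adjusted p = 0.413 with an estimated correlation, and 0 were lower without day 5 library 1 or 2. Astrocyte markers had 3 higher and 6 lower of 13, the same adjusted over the list alone (camera adjusted p = 0.301), with the glutamate transporters Slc1a2 at 1.69 and Slc1a3 at −1.18. Cholesterol genes had 6 higher and 2 lower of 19 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0632), with Ebp at 1.57 and Lss at −0.85. They had 2 higher and 4 lower on unscaled TPM, 11 and 3 with culture as a block, and 3 and 2 without day 5 library 2. The integrated stress response had 4 higher and 3 lower of 12 (the same adjusted over the list alone; camera adjusted p = 0.565), with Ddit3 at 1.12 and Phgdh at −2.30. Heat shock genes had 3 and 1 of 11 (the same adjusted over the list alone; camera adjusted p = 0.159), with Hsph1 at 1.39, and 6 and 1 with culture as a block. On unscaled TPM the median of all genes moved by −0.24 on the log2 scale, and 1808 genes were higher and 4135 lower at day 16. Genes lower at day 16 numbered 1703 without day 5 library 2 and 1852 without day 5 library 1.

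When silenced neurons were given Bic, immediate early transcripts had their highest values at 60 min. Fos stood at 8.87 and 55.0 TPM in the pair of 0 min libraries, 155 and 229 at 20 min, 493 and 494 at 60 min, and 58.2 and 262 at 360 min. Arc stood at 15.9 and 48.9 at 0 min, 234 and 416 at 60 min, and 26.4 and 63.6 at 360 min. Atf3, a stress-responsive transcription factor, was at 3.08 and 7.60 at 0 min, 101 and 114 at 60 min, and 97.7 and 89.8 at 360 min. Atf3 (log2 change 4.20, SE 0.41), Ier2 (3.31) and Gadd45g (2.72) were the 3 genes higher at 60 min in limma, with adjusted p values of 0.0311, 0.0339 and 0.0311. At 360 min Atf3 was higher as well (4.00, limma adjusted p = 0.0311). Bdnf stood at 2.86 and 22.9 at 0 min and at 29.7 and 30.7 at 360 min (log2 change 1.70, SE 0.68, limma adjusted p = 0.633).

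Counts of genes higher and lower in limma were 0 and 0 at 5 min, 1 and 3 at 20 min, 3 and 4 at 60 min, and 2 and 4 at 360 min, of 14345 tested. At 5 min 74 genes were higher and 441 lower at an unadjusted p under 0.05, together fewer than the share of 0.05 that chance gives. The other calls were chosen for naming after their values were seen, because they are few. They were Mir193a higher at 20 min, Mir7016 higher at 360 min, Mir6943, Mir328 and Mir669l lower at 20, 60 and 360 min, and Mirlet7c-1 lower at 60 and 360 min. Total RNA libraries measure such short genes poorly, so these calls are uncertain.

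Of the immediate early genes, 19 were higher at 60 min adjusted over the list alone and 3 over all genes. For this list camera gave an adjusted p = 9.93e-61, and an adjusted p = 0.131 with an estimated correlation. At 20 min 5 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 4.18e-10, and adjusted p = 0.681 with an estimated correlation). At 360 min they numbered 5 and 1 (camera adjusted p = 3.5e-05, and adjusted p = 0.584 with an estimated correlation). Late activity genes had 3 higher at 60 min adjusted over the list alone (camera adjusted p = 3.91e-17, and adjusted p = 0.343 with an estimated correlation). The integrated stress response had 5 higher at 360 min adjusted over the list alone (camera adjusted p = 0.000429, and adjusted p = 0.575 with an estimated correlation). Postsynaptic scaffolds had 9 lower at 60 min adjusted over the list alone (camera adjusted p = 0.000602, and adjusted p = 0.511 with an estimated correlation). Presynaptic vesicle genes had 6 lower at 60 min adjusted over the list alone (camera adjusted p = 3.23e-05, and adjusted p = 0.343 with an estimated correlation). These decreases were not particular to 60 min, since median log2 changes were −0.563, −0.485, −0.691 and −0.40 at the 4 times for scaffolds and −0.493, −0.43, −0.754 and −0.476 for presynaptic genes. Astrocyte markers had medians of −0.833, −1.03, −1.14 and −0.75 (camera adjusted p = 0.000602 at 60 min, and adjusted p = 0.511 with an estimated correlation). The astrocyte genes Gfap and Aqp4 stood at 44.6 and 6.08 TPM in the 0 min library without a date. They stood at 4.96 and 1.85 in the dated 0 min library, and at 2.12 to 5.23 and 1.14 to 2.61 later. The fall of these genes therefore rests on the undated library.

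Libraries of the time course differed in more than time. Pvalb stood at 2.10 to 2.62 TPM in the libraries of the earlier culture date and at 67.9 to 107 in those of the later date. The 45S precursor took 20.4% of the 5 min library, 17.7% of the earlier 20 min library and 15.9% of the later 60 min library, against 0.818% to 2.41% of the others. With these 3 libraries left out, limma called 0 genes at 20, 60 or 360 min. With culture date as a block 83 genes were higher and 88 lower at 5 min, 85 and 58 at 20 min, 59 and 68 at 60 min, and 102 and 44 at 360 min. With trimmed-mean scaling as well they were 2 and 0, 0 and 0, 11 and 1, and 0 and 0. Without the undated 0 min library the counts at the same times were 0 and 0, 1 and 0, 0 and 0, and 0 and 0. Without the dated 0 min library they were 5 and 5, 27 and 10, 32 and 20, and 48 and 17. The undated 0 min library forms a date of its own in the block, which leaves the dated library as the only baseline. At 5 min the block therefore compares 1 library with 1. It is not a separate check from leaving out the undated library. Median shifts against 0 min were −0.289 at 5 min and −0.267 at 60 min on the log2 scale.

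Across 13331 genes, changes at 360 min correlated with the 24 h difference of Bic and TTX at Pearson 0.435 and Spearman 0.404. Changes at 5, 20 and 60 min correlated with it at Pearson 0.29, 0.307 and 0.421. Genes are not independent replicates, and the undated 0 min library may come from the cultures of the 24 h experiment, so the comparisons may not be separate. Without the undated 0 min library the Pearson values were 0.0213, 0.0446, 0.156 and 0.203 at 5, 20, 60 and 360 min, and with culture date as a block they were 0.0177, 0.0997, 0.209 and 0.248. Of 980 genes that differed over 2-fold at 24 h, 89.4% had the same sign at 360 min, against 67.7% without the undated 0 min library and 71.3% with culture date as a block.

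Most of the H3K27ac peaks in the full list of silenced neurons overlapped a peak in the list of active ones. The deposited lists held 46587 peaks in Bic, 44677 in TTX and 47111 in untreated cells. Of the Bic peaks 65.12% overlapped a TTX peak by 1 bp or more and 16249 did not. Of the TTX peaks 68.7% overlapped a Bic peak and 13986 did not. Between the higher-scoring parts of both lists these shares were 36.65% of the Bic and 38.71% of the TTX peaks, and shortening both lists removes partners and so lowers them by design. Merged into 64645 regions, 28583 (44.22%) were present in all 3 lists, 9362 in Bic only, 8092 in TTX only and 5265 in untreated only. Peaks in a single list were narrower than shared ones, at a median of 711 against 1418 bp in Bic.

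Counts are given for 5 of the 6 regions covered by 5C. The Fos region held 25 Bic peaks outside the TTX list and 5 TTX peaks outside the Bic list, and the Bdnf region 16 and 9. The synaptogenim region, named as in the primer file, held 29 and 51, Arc 25 and 29, and neuroligin3 7 and 3. Within the 5C regions the highest score among Bic peaks outside the TTX list was at chr10:107369222-107369463 (mm9; score 1234, 19.4-fold over background, also in the untreated list). Next was chr10:107343228-107343457 (score 970, 15.5-fold). Each state had 1 immunoprecipitation, so these differences have no replicate check.

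Contacts measured by 5C differed between active and silenced neurons mostly in the synaptogenim region. The window pair at chr10:107980001-108000000 and chr10:108160001-108180000 (mm9) had an observed over expected contact of 2.89 ± 0.295 (SD, n = 4) in Bic, 1.89 ± 0.177 in untreated cells and 1.36 ± 0.0984 in TTX. A pair of the Bdnf region, at chr2:107860001-107880000 and chr2:108120001-108140000, had 3.42 ± 0.192, 2.35 ± 0.102 and 1.75 ± 0.209. The pair at chr10:108940001-108960000 and chr10:109140001-109160000 ran the other way, with 0.731 ± 0.0668 in Bic, 1.03 ± 0.0767 in untreated cells and 1.34 ± 0.078 in TTX. Of 39533 window pairs tested in edgeR, 154 were higher and 68 lower in Bic than in TTX, with a median size of 0.556 on the log2 scale.

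The first pair on chromosome 10 had a log2 change of 1.08 (edgeR adjusted p = 0.000294), and both of its windows held Bic peaks absent from TTX. The window at 107980001 took part in 21 of the 154 higher pairs, including those with the windows at 108100001 (0.96), 108080001 (0.72) and 108200001 (1.19). The Bdnf pair had a log2 change of 0.96 (edgeR adjusted p = 0.000312), and both of its windows also held Bic peaks absent from TTX. The lower pair had a log2 change of −0.87 (edgeR adjusted p = 0.00129) and TTX peaks absent from Bic at both ends. Other lower pairs joined the windows at 109020001 and 109140001 (−0.85), 108980001 and 109120001 (−0.70), 109020001 and 109100001 (−0.56), and 109020001 and 109120001 (−0.59). In 5 of the 6 regions the higher and lower counts were 96 and 45 of 7598 for synaptogenim, 35 and 8 of 13552 for Bdnf, 8 and 2 of 2766 for Fos, 6 and 2 of 2031 for neuroligin3, and 2 and 6 of 6530 for Arc. Called pairs lay at a median distance of 180 kb, against 740 kb for all pairs.

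**Figure D3:**
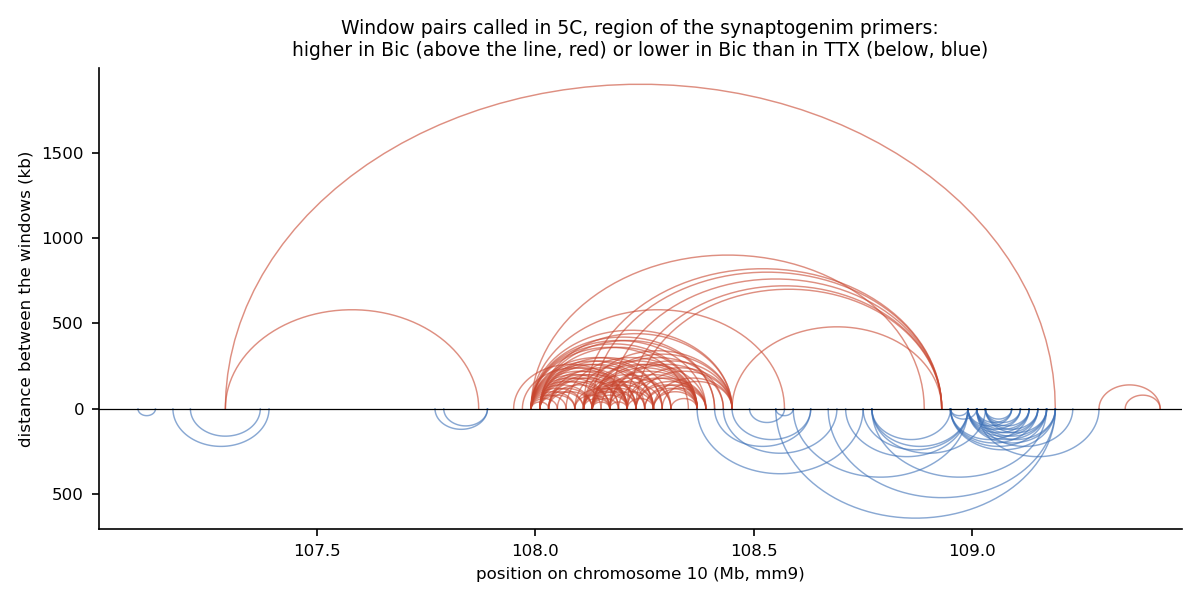
Window pairs called in Bic against TTX in the synaptogenim region on chromosome 10, with position in Mb (mm9) on the horizontal axis and distance between the windows in kb on the vertical axis. Arcs above the line are the 96 pairs higher in Bic and arcs below it the 45 lower pairs.

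Windows with state-specific H3K27ac peaks were common among the called pairs. Of the 154 pairs higher in Bic, 106 (68.8%) had an end with a Bic peak absent from TTX, against 31.2% in sets matched on region and distance (p = 5e-04, the smallest that 2000 permutation sets can give). Of the 68 lower pairs 44 (64.7%) had an end with a TTX peak absent from Bic, against 44.1% in matched sets (permutation p = 5e-04, the smallest possible). Peaks of any kind were also more frequent, at an end of 96.1% of the higher pairs (72.1% in matched sets) and 91.2% of the lower (77.9%). They were at both ends of 75.3% of the higher pairs (31.2%) and 50% of the lower (35.3%). Peaks of the opposite state were not more frequent. TTX peaks absent from Bic were at an end of 37% of the higher pairs (40.3%), and Bic peaks absent from TTX at an end of 10.3% of the lower (33.8%). Called pairs share windows, 1 of which is in 21 of the 154 higher pairs, and matched sets were drawn pair by pair, so these p values are too small. In the classes that follow, Bic-only peaks are those absent from TTX and TTX-only peaks those absent from Bic, whether or not the untreated list holds them. Over all 1056 window pairs with Bic-only peaks at both ends, the mean log2 observed over expected was −0.00726 ± 0.0568 in Bic and −0.133 ± 0.0725 in TTX. Their difference was 0.125 (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and 0.143 after adjustment over the classes), with 0.0718 in the earlier and 0.179 in the later culture date. Pairs with TTX-only peaks differed by −0.0524 (exact permutation p = 0.286) and pairs with shared peaks by −0.0499 (exact permutation p = 0.543). In the earlier and the later date these were −0.104 and −0.000743 for TTX-only peaks and −0.116 and 0.0164 for shared peaks.

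Each of the 154 higher and 68 lower pairs had the same direction in both culture dates, whose libraries they were called on, with medians of 0.581 and −0.579 in the earlier and 0.556 and −0.489 in the later. In edgeR the earlier date alone called 1407 higher and 2256 lower, and the later date alone 0 and 0. The later date had 2006 at an unadjusted p under 0.05, about the share of 0.05 that chance gives. In the earlier date outlier primer pairs took 11.3% and 11.6% of the counts within regions in Bic but 5.04% and 4.18% in TTX. State and share cannot be told apart there. In the later date the shares were 15.9% and 3.97% in Bic and 14.4% and 6.45% in TTX. Without Bic library 1, 2, 3 or 4 the higher and lower calls over both dates numbered 69 and 19, 97 and 29, 80 and 30, and 237 and 205. Without TTX library 1, 2, 3 or 4 they were 67 and 19, 74 and 19, 90 and 36, and 71 and 20. DESeq2 called 416 pairs higher and 372 lower. It gave no adjusted p for 22994 of the pairs, so its adjustment covered fewer pairs than that of edgeR. In edgeR trimmed-mean library factors alone left 5 and 0, and region totals alone 50 and 8.

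Against untreated cells edgeR called 0 window pairs for Bic (2862, or 7.24%, at an unadjusted p under 0.05, where chance gives a share of about 0.05). DESeq2 called 111 higher and 80 lower, and it gave no adjusted p for 32191 of the pairs. Without Bic library 4 edgeR called 16 higher and 4 lower. For TTX against untreated cells edgeR called 0 (1491, or 3.77%, at an unadjusted p under 0.05, below the share that chance gives). DESeq2 called 0 higher and 11 lower, and it gave no adjusted p for 31424 of the pairs. A score of the pairs called between Bic and TTX, the mean log2 observed over expected of the higher pairs minus that of the lower pairs, was 0.346 to 0.703 in untreated cells. It was 0.955 to 1.32 in Bic and 0.00197 to 0.0325 in TTX, the libraries that the pairs were called on.

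In the 5C time course, which has 1 library per time and shares none with the 24 h states, the pairs called at 24 h were compared with matched pairs, a comparison that holds no spread between libraries and treats pairs that share windows as separate. The 154 higher pairs had median log2 changes from 0 min of −0.00681 at 5 min, −0.0309 at 20 min (the opposite direction, at percentile 1.41 of the matched sets), 0.146 at 60 min and 0.125 at 360 min, the last 2 above all 10000 matched sets. The 68 lower pairs had medians of −0.0545, −0.153, −0.196 and −0.224, at percentile 0.21 of the matched sets at 5 min and below all of them from 20 min on. Among the 263 higher pairs called with the share of outlier primer pairs as a covariate, the median at 20 min was −0.00268, at percentile 23.83. The score was 0.0145 at 0 min and 0.383 at 360 min.

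**Figure D4:**
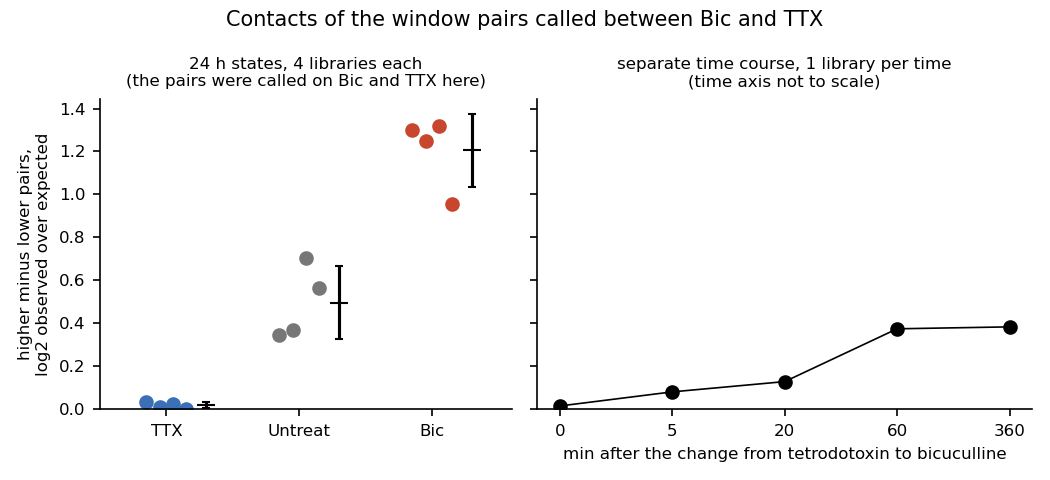
Score of the window pairs called in Bic against TTX for each 5C library of the 24 h states, with points for libraries and the mean and SD for each state, and of the time course, with minutes after the change to Bic on the horizontal axis. The time course libraries stood at 0.0145 at 0 min and 0.383 at 360 min, the latter within the range of untreated cells at 24 h.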

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

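In this part, the splits of the 5C libraries with the share of outlier primer pairs as a covariate were written down before their result was seen, and the other tests were chosen after the result was seen. Of 57 groups of 4 libraries 1 held a library far from the others: at the window pair of chr10:107980001 and chr10:108160001 (mm9), TTX library 4 had an observed over expected contact of 1.216, against 1.393 to 1.42 in the other TTX libraries. Chance sets a library apart in this way in about 1 in 20 groups.

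The 154 higher and 68 lower window pairs called by 5C between Bic and TTX came from libraries that also differed in the share of counts on 79 outlier primer pairs, from 3.48% to 15.9%, and over the 12 libraries the first principal component (27.7%) correlated with the log2 of that share (Pearson −0.928, permutation p = 1e-05, the smallest 100000 resamples give; Spearman −0.93, permutation p = 8e-05; −0.925 without the 2 farthest libraries). Splits of the 8 libraries do not exclude chance: 2 of 35 gave as many calls, with 222 in the real split and 478 in another that set the 4 libraries with the highest shares against the rest, and with the share as a covariate 2 of 35 did, with 400 in the real split and 471 in the split by culture date, and among the 18 splits even over the dates, too few for a share under 0.05, the highest other was 478 without the covariate and 4 with it. The share as the whole cause is argued against by the fit with it as a covariate, where 100% of the 222 pairs were called again in the same direction while 3864 pairs followed the share. Culture date as the whole cause is argued against, since each state had 2 libraries of each date and 97.7% of the 222 pairs (217) were called again with date as a covariate. An effect of the treatment stays open, because the separate time course, where the higher pairs moved by 0.125 and the lower pairs by −0.224 at 360 min, has 1 library per time and so no spread between libraries.

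For Bic against untreated cells edgeR called 0 window pairs. An unadjusted p under 0.05 was found for 2862 (7.24%), where chance gives a share of about 0.05. DESeq2 called 111 higher and 80 lower, with no adjusted p for 32191 pairs. A count of 0 is reached by all 35 splits, so they say nothing about chance. The highest other count was 970, in a split even over the culture dates. For TTX against untreated cells edgeR called 0, with 1491 (3.77%) at an unadjusted p under 0.05, below the share that chance gives. DESeq2 called 11 lower, with no adjusted p for 31424 pairs. Again all 35 splits reach the count of 0 in edgeR, the highest other being 567 in the split by culture date. Counts of this size in other splits point to a structure of the samples. With culture date as a covariate edgeR called 1 pair higher and 0 lower for Bic and 0 for TTX.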

How the results depend on the processing

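Alternatives described here as added, and the leading tests of RNA on TPM, were chosen after seeing the data, and all others before. Counts below are higher and then lower, and for results that moved the cause was not tested. Among genes named in the RNA contrasts, 2595 of 2820 values kept their direction and call when a library was left out (152 lost the call, 27 gained one, 46 changed sign), as did 3163 of 3357 under other settings (48 lost, 126 gained, 20 changed sign). In the time course these were 2585 of 2658 (18 lost, 20 gained, 35 changed sign) and 2527 of 2626 (15 lost, 12 gained, 72 changed sign), and for named window pairs 120 of 120 and 100 of 120 (20 lost).

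RNA on unscaled TPM gave 2497 and 458 for Bic against untreated cells (1596 and 1405), 372 lower for TTX against untreated cells (980) and 1808 higher at day 16 (3071). A minimum TPM of 5 (added) gave 1033 genes off the midpoint (1691), with fewer genes tested. Fitting only the groups compared gave 269 higher in TTX than in untreated cells (501). Culture as a block (added) gave 3838 and 3523 for Bic against TTX, 4188 and 3415 for Bic against untreated, 3490 and 3119 for TTX against untreated, and 7011 for RNA Untreat off the Bic-TTX midpoint. The earlier culture alone (added) gave 3637 and 3520, 3962 and 3685, 3246 and 3109, and 6880. That fit holds libraries 1 and 2 of each state, from a single culture date, so its tests do not measure the spread between cultures. A 2-fold minimum gave 731 and 320, 591 and 194, 99 and 242, and 213, and 1386 and 1366 at day 16. Leaving out 1 library at a time gave ranges of 1231 to 2106 higher and 896 to 1658 lower for Bic against TTX, 780 to 1924 and 642 to 1780 for Bic against untreated, 140 to 654 and 327 to 1257 for TTX against untreated, 282 to 2263 for RNA Untreat off the Bic-TTX midpoint, and 1703 to 2929 lower at day 16.

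Time course counts were 0 and 0, 1 and 3, 3 and 4, and 2 and 4 at 5, 20, 60 and 360 min. A pseudocount of 0.1 gave 1 and 1 at 5 min, 0 and 0 at 20 min and 1 and 1 at 360 min, and a pseudocount of 5 gave 1 and 1 at 5 min and 1 lower at 20 min. Without a filter there were 26 and 4 at 5 min and 0 higher at 60 min. A minimum TPM of 5 gave 0 and 0 at 20 min, 0 lower at 60 min and 1 and 0 at 360 min. Quantile and trimmed-mean scaling each gave 1 lower at 5 min, 0 lower at 20 min, 2 lower at 60 min and 0 and 1 at 360 min. Culture date as a block (added) gave 83 and 88, 85 and 58, 59 and 68, and 102 and 44, and correlations with the 24 h difference of 0.0177, 0.0997, 0.209 and 0.248 (0.29, 0.307, 0.421 and 0.435). With trimmed-mean scaling as well (added) there were 2 higher at 5 min, 0 and 0 at 20 min, 11 and 1 at 60 min, and 0 and 0 at 360 min. Without the libraries above 10% 45S RNA (added) there were 0 and 0 at 20, 60 and 360 min. Leaving out 1 library gave 0 to 5 and 0 to 5 at 5 min, 0 to 27 and 0 to 10 at 20 min, 0 to 32 and 0 to 20 at 60 min, and 0 to 48 and 0 to 17 at 360 min. The correlations ran from 0.0213 to 0.399, 0.0446 to 0.405, 0.156 to 0.493 and 0.203 to 0.501. Culture date as a block and leaving out the undated 0 min library both rest on the dated 0 min library alone.

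For 5C, Bic against TTX stood at 154 and 68 and the contrasts with untreated cells at 0. Windows of 10 kb gave 24 lower, and windows of 40 kb 124 lower, with 7 and 7 for Bic against untreated cells. Library factors alone gave 5 and 0 and region totals alone 50 and 8. Culture date as a covariate gave 175 and 80, with 217 of the 222 pairs among them, and 1 higher for Bic against untreated cells. The earlier date alone gave 1407 and 2256, and 1354 and 2213 for Bic against untreated cells, and the later date alone 0 and 0. In the earlier date both Bic libraries had higher shares of outlier primer pairs than the TTX and untreated libraries, so state and share cannot be told apart there. Without the outlier primer pairs (added) there were 234 and 124, and 8 and 2 for Bic against untreated cells. The share of outlier primer pairs as a covariate (added) gave 263 and 137, with 20 and 3 for Bic and 3 lower for TTX against untreated cells. Share and date together (added) gave 346 and 205, 60 and 19, and 2 and 14. DESeq2 gave 416 and 372, 111 and 80, and 11 lower for TTX against untreated cells. It gave no adjusted p for 22994, 32191 and 31424 pairs of these contrasts, so its adjustment covered fewer pairs than that of edgeR. Leaving out 1 library gave 67 to 237 and 19 to 205, and for Bic against untreated cells 0 to 16 and 0 to 4. The stricter part of the peaks by score gave 8550 untreated peaks outside both other lists (5265), with fewer peaks in those lists.

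Contacts by H3K27ac class also changed sign without being called. In windows of 10 kb, pairs with shared peaks stood at 0.0265 for Bic against TTX, 0.0203 for Bic against untreated cells and −0.00613 for TTX against untreated cells, where pairs without peaks stood at 0.00319. Leaving out 1 library gave −0.0695 to 0.023 for shared peaks in Bic against untreated cells. In TTX against untreated cells it gave −0.0196 to 0.0811 for shared peaks, −0.0326 to 0.0349 for a peak at 1 end, −0.0388 to 0.0352 for no peak and −0.00063 to 0.0507 for TTX-only peaks.

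Named genes that changed sign, none of them called with either sign, are given as log2 changes. On unscaled TPM these were Acta2 0.0418 (Bic against TTX), Syt1 0.16, Tagln 0.14 (Bic against untreated), Mbp 0.0407, Cnp 0.0191, Olig2 0.064, Olig1 0.12 (TTX against untreated). With upper-quartile scaling they were Olig1 −0.00418 (Bic against TTX), Olig2 0.00843, Olig1 0.0636 (TTX against untreated). Without a filter they were Cnp −0.0017, Olig1 −0.00251 (Bic against untreated). At a minimum TPM of 5 (added) they were Syt1 0.00469, Tagln 0.00500 (Bic against untreated), Olig1 0.0323 (TTX against untreated). The earlier culture alone (added) gave Birc5 −0.0545 (Bic against TTX), Olig1 −0.0532, C1qc −0.13 (Bic against untreated), Nlgn3 −0.0486, Mbp 0.0901 (TTX against untreated). Leaving out 1 library gave these ranges: for Bic against TTX, Cnp −0.0153 to 0.32, Olig1 −0.23 to 0.32, C1qb −0.16 to 0.45, Tyrobp −0.52 to 0.25, Acta2 −0.13 to 0.0725, Birc5 −0.0689 to 0.12, and for Bic against untreated, Syt1 −0.30 to 0.16, Olig2 −0.19 to 0.31, Cnp −0.14 to 0.19, Olig1 −0.35 to 0.29, Tyrobp −0.0368 to 0.56, C1qa −0.50 to 0.0787, C1qc −0.35 to 0.38, Dcn −0.60 to 0.0445, Tagln −0.27 to 0.0818, and for TTX against untreated, Nlgn3 −0.22 to 0.19, Mbp −0.18 to 0.0164, Olig2 −0.40 to 0.10, Olig1 −0.41 to 0.17, C1qa −0.10 to 0.47, C1qb −0.41 to 0.17, Birc5 −0.00179 to 0.21.

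Quantile scaling of the time course gave Olig1 0.0319, Ccnb1 0.00589, Prc1 0.0658, Birc5 0.0386 (5 min), C1qc 0.0907, Tpx2 0.0536 (60 min). Trimmed-mean scaling gave Prc1 0.0328, Birc5 0.0284 (5 min), C1qc 0.0367, Tpx2 0.0285 (60 min). Culture date as a block (added) gave Ccn1 −0.32, Fos −0.0527, Bdnf −0.41, Idi1 −0.10, Tagln −0.16, Acta2 −0.19, Col1a2 −0.14, Cdk1 −0.0954 (5 min), Cyp51 −0.00013, Reln −0.22, Tagln −0.17, Col1a1 −0.19, Acta2 −0.16, Atf4 −0.053, Hspb1 −0.0862 (20 min), Bdnf −0.0132, Tmem119 −0.13, Tagln −0.11, Acta2 −0.036, Pdgfrb −0.43, Rgs5 −0.37 (60 min), Apoe 0.14, Tmem119 −0.14, Hsp90aa1 −0.0421, Hspd1 −0.11 (360 min). Fitting without the libraries above 10% 45S RNA (added) gave Syt1 0.23, C1qa 0.28, C1qc 0.12 (20 min), Prc1 0.00226 (60 min). Trimmed-mean scaling and culture date together (added) gave Sst 0.11, Bdnf −0.0594, Gabra3 0.0196, Dhcr7 0.0111, Acat2 0.0115, Birc5 0.19, Ddit4 0.0912, Atf5 0.14, Sesn2 0.0307 (5 min), Syt1 0.0895, Reln −0.11, Tagln −0.0539, Col1a1 −0.11, Acta2 −0.0413 (20 min), Grik4 0.0205, Grik5 0.00756, Ebp 0.10, Tubb2a 0.0588, Tubb3 0.0539, Calb2 0.000307, Vip 0.0392, Aldoc 0.12, Olig1 0.057, C1qb 0.0402, C1qc 0.19, Pdgfrb −0.15, Rgs5 −0.13, Birc5 0.20, Phgdh 0.0918 (60 min), Aldoc 0.0905, Apoe 0.24, Tmem119 −0.11, Hspd1 −0.0108 (360 min). Leaving out 1 library gave these ranges at 5 min: Ccn1 −0.32 to 3.88, Fos −0.0527 to 2.45, Bdnf −0.41 to 2.22, Idi1 −0.10 to 1.42, Tagln −0.16 to 4.91, Acta2 −0.19 to 5.16, Col1a2 −0.14 to 0.71, Ccnb1 −0.55 to 0.077, Cdk1 −0.0954 to 0.63. At 20 min they were Syt1 −0.50 to 0.23, Reln −0.00314 to 1.32, C1qa −1.30 to 0.28, C1qc −0.82 to 0.15, Tagln −0.64 to 4.42, Acta2 −0.89 to 4.46, Tpx2 −0.000677 to 0.55, Hspb1 −0.22 to 3.53. At 60 min they were Bdnf −0.0696 to 2.56, C1qb −0.99 to 0.15, C1qc −0.74 to 0.31, Tagln −0.58 to 4.49, Acta2 −0.76 to 4.58, Rgs5 −0.20 to 1.46, Prc1 −0.50 to 0.00226, Kif11 −0.0675 to 0.47, Tpx2 −0.41 to 0.15, Hspb1 −0.0937 to 3.65. At 360 min they were Arc −0.24 to 1.31, Olig1 −1.17 to 0.0226, Ctss −0.31 to 0.89, Acta2 −0.34 to 5.01.

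Whether replicate numbers pair the 5C libraries stays open. Same-numbered libraries of different states deviated with correlations of −0.0959 to 0.325 (12 pairs, median 0.134). Medians were 0.0342 for the same culture date under another number and −0.0658 for another date. Not every library correlated best with its own number. The number as a block gave 180 and 87 for Bic against TTX and 1 higher for Bic against untreated cells, and it changed no other call count past 1.5 times. No paired analysis was possible because the RNA columns of the 24 h states carry numbers that restart in each culture and only 1 column of the time course carries a number, so culture or culture date was the block there. Count models for RNA were not run because the table holds TPM, and the median-ratio and upper-quartile factors were applied in limma instead. The planned CPM filter needs read counts, and only when applied to TPM does it equal the filter used. The 5C test recovered 4.71% of simulated 1.5-fold changes, and the depth behind RNA values is unknown.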

Other observations

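Of the tests in this part, only that of the epidermal genes in the time course was written down before its result was seen, and the other tests were chosen after. Neurons given Bic differed from untreated ones in single genes of the synapse and of chloride transport. The vesicular glutamate transporter Slc17a6 stood at 13.2 ± 3.04 TPM (SD, n = 3) in Bic and 1.71 ± 0.893 in untreated cells. The chloride exporter Slc12a5 ranged from 85.0 to 145 TPM in untreated cells and from 40.2 to 67.7 in Bic (log2 change −1.06, SE 0.28, limma adjusted p = 0.0292), and the kinase subunit Camk2b fell from 483 ± 78.5 to 264 ± 53.2. Presynaptic genes had 3 higher and 2 lower of 23 and postsynaptic scaffolds 2 and 2 of 20, the same adjusted over the list alone (camera adjusted p = 0.261 for both). With culture as a block they had 4 and 13, and 5 and 13 (camera adjusted p = 0.0193 and 0.0252, and 0.364 for both with the estimated correlation). In TTX against untreated cells limma called 0 genes of either list, and with culture as a block 5 higher and 8 lower, and 2 and 7.

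Among the merged H3K27ac regions, 6645 were listed in Bic and untreated cells without TTX, 5620 in TTX and untreated cells without Bic, and 1078 in Bic and TTX without untreated cells. With 1 peak list per state these numbers have no replicate check.

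The epidermal genes Lce1g, Lce1i, Lce3c, Crct1 and Krt6a were at 19.3 TPM or more in every Bic library. They were at 3.38 or less in the other libraries of the 24 h states. Of the Lce, Sprr and Crct1 families 9 of 9 tested genes were higher in Bic. Family members near 0 in TTX and untreated cells pass the filter only through the Bic libraries, so this count is largely set by the filter. Members that were low in every state were not tested. Keratinocytes in the Bic cultures are argued against by the keratins Krt5, Krt14, Krt1 and Krt10, whose highest value in any Bic library was 1.88 against 61.8 for the lowest of Lce1g, and by 16 keratinocyte markers at a median of 0.227 TPM in Bic and 0.152 in TTX. Krt5 was nonetheless at 0.777 to 1.17 in Bic and at 0.104 or less in the other libraries of the 24 h states. A single odd culture is argued against by the value of 19.3, the lowest in any Bic library of either culture. An effect of Bic may account for the pattern, but in the time course the set had a mean log2(TPM + 1) of 1.1 and 1.9 at 360 min and 0.169 and 1.11 at 0 min, and these 0 min libraries are too unlike to decide.

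The pair of 0 min libraries of the RNA time course differed in activity genes, with a mean log2(TPM + 1) of the immediate early list of 3.145 in the undated and 4.325 in the dated library, and in genes of other cells, with Acta2 at 4.33 and 216 TPM, Gfap at 44.6 and 4.96, and Apoe at 1000 and 295. A difference in ribosomal RNA is argued against by 45S shares only 0.114 percentage points apart. The undated library may come from the cultures of the 24 h experiment: across 16026 genes its lowest correlation with a 24 h TTX library was 0.9711, above its highest with a time course library, 0.9573, and Acta2 stood at 2.65 to 3.75 TPM and Gfap at 33.4 to 52.8 in the 24 h TTX libraries. Whether the dated library holds a sample taken later cannot be told apart from a weaker silencing of that culture, since its 4.325 lies below the lower 20 min library (4.558) by less than the 20 min libraries differ (4.558 and 5.193), and this concerns the activity genes alone. In each case changes measured from 0 min depend on which of the pair is used.

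For the RNA contrasts of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and 1 of 10 in each, the real one, gave as many calls. The real split called 3554 genes for Bic against TTX and the highest other 2, and for Bic against untreated cells 3001 and 1. For TTX against untreated cells the numbers were 1481 and 2, and for the 2 ages 5951 and 2. Every other split mixes the 2 groups compared, which widens the spread and lowers its count in advance. The low counts of the other splits therefore say nothing about chance. For untreated cells off the midpoint of Bic and TTX, 2 of 100 drawn splits gave as many as the real 1691, but most splits mix the 3 states, which widens the spread, so this share does not exclude chance. The highest other, 2107, put the 3 Bic libraries in the place of the untreated ones.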
